A study of Mus musculus with 28 samples.

How the data were processed

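RNA was measured in 7 lines of mouse embryonic stem (ES) cells, each carrying a transgene that doxycycline (Dox) keeps off, and each grown with Dox (transgene off) or without Dox (transgene on). Per the labels, the cells were at passage 25, in medium with LIF and with puromycin at 1.5 µg/ml, and Dox was used at 0.2 µg/ml. Cells of each line were split into 6 wells, 3 per condition, and were harvested 48 h after the final wash (day 2). RNA of 2 wells per line and condition was hybridised, which gave 28 arrays in 14 groups of 2. Every array carried the sample in Cy3 and a common reference in Cy5. The sample labels describe the reference as 2 parts of a pool of RNA from 11 cultured mouse cell lines and 1 part of ES cell RNA. Since the sample was in Cy3 on all arrays, a dye effect that differs between probes stays in every log ratio, but cancels in a difference between arrays of the same orientation if it is the same on each.

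The scanner files hold 43451 spots of a 2-colour Agilent design with probes of 60 bases. The deposited mean and background signals of each spot are intensity values per the file headers, read with Agilent Feature Extraction 9.5.1.1 under the GE2-v5_95 protocol, before any normalization. The processed signals in the same files, also intensity per the file headers, had background subtracted and dyes balanced within the array by that software. The deposited detection, saturation and spot quality columns are other values, namely flags of 0 or 1 per the file headers. A table of the authors holds 25030 of the probes with scale and processing unstated. Set against the scanner values of the same spots, the values deposited by the authors are log10 signals of the Cy3 channel from which the deviation of the Cy5 reference from its mean over the arrays had been taken off. On each array 90.5% to 100% of bright spots lay within 0.01 of that quantity. In the order with Dox replicates 1 and 2, then without Dox replicates 1 and 2, the column medians in log10 units were 2.26, 2.27, 2.26 and 2.25 in the Tcl1 line and 2.28, 2.28, 2.28 and 2.27 in the Etv5 line. They were 2.27, 2.27, 2.27 and 2.27 in the Tbx3 line, 2.28, 2.28, 2.28 and 2.28 in the Jarid2 line, and 2.27, 2.27, 2.27 and 2.28 in the Jmjd2c line. The Ctbp2 columns had medians of 2.28, 2.27, 2.28 and 2.28, and the Mettl5 columns 2.27, 2.27, 2.27 and 2.27. How low values were bounded in that table stays unknown.

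The background was corrected with normexp (offset 50), and the log ratio was normalized with loess within each array, with control spots and spots with a quality flag at weight 0 (limma 3.58.1 in R 4.3.3, with the packages statmod 1.5.0 and, for reading, data.table in version 1.17.8). Values are log2 of sample over reference. Spots of the same probe were averaged, which left 42006 probes. A probe was tested if it was well above background in Cy3 on both arrays of at least 1 of the 14 groups, which kept 28884 probes. On all 28 arrays 23703 probes were well above background, and no spot was saturated. The number of arrays, 2 per group, limits the precision.

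The gene name column of the scanner files repeats the probe ID, its description reads Unknown for all probes, and 0 of the 42006 IDs matched the reference table of genes. The unit of every test is therefore the probe and not the gene, no gene is named for a probe, and genome positions are not given. The check of each induced gene, the 27 gene lists fixed beforehand, which include markers of other cell types, and the mean over the probes of a gene were not run. Any transgene's own transcript is for this reason not analysed here, and the assignment of arrays to lines and cultures rests on the labels.

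A group-means model was fitted to each probe over all 28 arrays with limma (lmFit, eBayes), with 14 residual degrees of freedom and 4.93 prior degrees of freedom. Each line's culture without Dox was compared with its culture with Dox, two-sided, and a probe passed at a Benjamini-Hochberg adjusted p under 0.05. A change is log2 without Dox minus log2 with Dox. The difference between lines in the response, and that between lines with Dox, were tested with limma's moderated F test over 6 contrasts. What all lines share was tested on 7 values per probe, a single mean change per line, since the line is the replicate for that question. The similarity of the lines is Pearson's r across probes over the 21 pairs of lines, without a test, since probes are not independent replicates. The probes to name were, per line, the 10 with the largest rise and the 10 with the largest fall among those that passed, whose groups did not overlap and which were well above background on both arrays of the higher group and not saturated. Where fewer than 5 passed in all, the 5 with the smallest p were taken. Because the probes have no gene names, at most 2 probes with a rise and 2 with a fall are printed per line, and the rest are summarised. A probe that is well above background on neither array of a group has only a bound there, computed per channel after loess and Aquantile, and open to dye bias.

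The tests, thresholds, filter, rule for naming probes and most alternatives were fixed before the data were examined. The alternatives were the processed signals of the scanner software, median centring in place of loess, Aquantile between arrays, the Cy3 channel alone (processed signals minus the 75th percentile of each array), the table of the authors restricted to tested probes, no filter and a stricter filter, slide as a random block, a trended and robust eBayes, a replicate block, the 4 arrays of a line alone, a change of at least 1.5-fold, the change minus the mean of the other 6 lines, and leaving out each array. After the data were seen, the removal of the trend with probe GC content (lowess, span 0.3), the omission of the Tbx3 line, the fits of the Cy5 reference channel alone and of the Cy3 channel alone after quantile normalization, the count of directions without the calls of the Tbx3 line, and the probe groups above and below the reference were added. The probe groups were tested with camera at a preset correlation of 0.01 and with an estimated correlation.

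The labels place 7 lines on 8 slides. In 6 lines all arrays lie on 1 slide, so the comparison of cultures is made within a slide, but the cultures with Dox lie at positions 1 and 2 and those without Dox at positions 3 and 4. Culture and position cannot be told apart there. In the Tbx3 line, without Dox replicate 1 lies on a slide of its own. Replicate numbers were not taken as pairs, since well letters and numbers did not match in the Jarid2, Ctbp2 and Mettl5 lines. The correlation across probes of the deviations of arrays with the same number was 0.43 in the Tcl1 line, 0.17 in the Tbx3 line and between -0.06 and 0.05 in the others.

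The fit was tested on simulated data with 200 changed probes among 28839 and the measured noise level. Noise was drawn independently for each array, with a single spread per probe for all arrays. In the real data the SD of the difference between replicates was 0.24 and 0.22 in the Tbx3 line and at most 0.14 elsewhere. Deviations of arrays with the same number correlated at 0.43 in the Tcl1 line. The shares below may thus not hold for the real lines, least of all for Tbx3. In a single line it recovered 48% of probes changed 1.25-fold, 92% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 4.52% of calls false. For the difference between lines it recovered 6%, 76%, 98% and 100% at the same sizes, and for the shared response 96% at 1.25-fold and 100% above that, with 6.60% of calls false. For the shared response the changes of the 7 lines were drawn independently, while the real ones correlated between lines at r of -0.23 to 0.42. That recovery may not hold for the real lines, so that a lack of calls does not exclude shared changes of these sizes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.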

Results

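RNA levels were measured on 28 2-colour arrays in 7 mouse ES cell lines, each a single clone with 1 transgene under Dox control, to ask what each transgene does to the transcripts of ES cells. Each line was arrayed in 2 cultures with Dox and 2 without Dox, harvested 48 h after the final wash. The transgenes encode Tcl1, a co-activator of the kinase Akt; Etv5, an ETS transcription factor; Tbx3, a T-box transcription factor; Jarid2, a component of Polycomb complexes; Jmjd2c, a histone demethylase; Ctbp2, a transcriptional corepressor; and Mettl5, a ribosomal RNA methyltransferase. The median Cy3 spot signal ranged from 81.3 to 117 over the arrays, at 1.77 to 2.80 times the median local background, and between 25428 and 28841 of the 42006 probes were well above background per array. Replicate arrays correlated across probes at r of 0.972 to 0.997. The SD of the difference between replicates was 0.24 and 0.22 (log2) in the Tbx3 line with and without Dox, and at most 0.14 in the other lines. Probes are given by their ID and 60-base sequence, as their genes are not named here, and each value is a log2 ratio of sample over reference as mean ± SD with n = 2 arrays. In each line, 33.3% of probes would have groups that do not overlap by chance. Changes of the Tbx3 line set beside those of other lines are from all its arrays unless stated. They are thus confounded with the slide of its without Dox replicate 1.

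In the Tcl1 line, 826 probes rose and 1114 fell without Dox among 28883 tested. Of the 113 that changed at least 1.5-fold, 13 rose and 100 fell, and 9 changed at least 2-fold. Z00036262-1 (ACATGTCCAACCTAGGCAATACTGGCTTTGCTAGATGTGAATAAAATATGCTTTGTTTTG) had the largest rise, from -1.63 ± 0.10 with Dox to 0.13 ± 0.03 without, a change of 1.76 (3.39-fold, SE 0.09, adjusted p = 5.2e-10). Z00059271-1 (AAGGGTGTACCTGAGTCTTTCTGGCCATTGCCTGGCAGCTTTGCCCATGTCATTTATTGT) rose from -2.00 ± 0.06 to -0.54 ± 0.05, by 1.46 (SE 0.10, adjusted p = 3.0e-08). Z00031338-1 (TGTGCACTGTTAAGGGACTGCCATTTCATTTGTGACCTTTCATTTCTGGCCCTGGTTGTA) fell by 1.38, from 0.92 ± 0.01 to -0.46 ± 0.22 (SE 0.07, adjusted p = 8.3e-10). Z00076304-1 (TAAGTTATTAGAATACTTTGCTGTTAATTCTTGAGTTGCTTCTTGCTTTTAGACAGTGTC) fell by 1.24, from 0.50 ± 0.21 to -0.73 ± 0.07 (SE 0.11, adjusted p = 4.2e-07). Both of the probes that fell were also lower with Dox in this line than in the others, where Z00031338-1 lay between 2.90 and 3.77 and Z00076304-1 between 2.59 and 3.60. The same held for both probes that rose. With Dox, Z00036262-1 lay between -0.18 and 0.55 in the other lines and Z00059271-1 between -0.66 and -0.02. Their levels without Dox in the Tcl1 line, 0.13 and -0.54, lay within these ranges and not above them. The 10 largest rises ranged from 0.61 to 1.76 and the 10 largest falls from -0.95 to -1.38, all 20 past the test of the difference between lines.

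The probes that passed in the Tcl1 line had a median size of 0.30 (log2). Over all probes of the line the groups did not overlap for 44.4%. Differences between cultures made from separate pairs of arrays correlated across all probes at r = 0.58. With median centring in place of loess 505 probes passed, with the 4 arrays of the line alone 196, and without the arrays of the Tbx3 line, a fit added after the data were seen, 4275. Leaving out with Dox replicate 1 gave 952 and leaving out without Dox replicate 1 gave 908. The balance depended on single arrays, with 432 higher and 1060 lower on leaving out with-Dox replicate 2, but 852 higher and 749 lower on leaving out without-Dox replicate 2.

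Removal of Dox in the Etv5 line came with a rise of 652 probes and a fall of 1001 among 28883 tested. Most were small, with a median size of 0.28 (log2), and of the 49 that changed at least 1.5-fold, 27 rose and 22 fell. Z00000270-1 (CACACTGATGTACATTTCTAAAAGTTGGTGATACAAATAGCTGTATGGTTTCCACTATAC) rose from 1.22 ± 0.13 to 2.60 ± 0.11, a change of 1.38 (2.60-fold, SE 0.14, adjusted p = 9.6e-06). Z00026923-1 (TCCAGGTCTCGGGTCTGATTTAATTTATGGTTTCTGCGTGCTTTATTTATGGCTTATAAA) rose by 0.96 (SE 0.09, adjusted p = 4.7e-06), from -0.79 ± 0.01 to 0.17 ± 0.09. It also rose by 0.35 in the Ctbp2 line (adjusted p = 0.025) and fell by 0.36 in the Tcl1 line (adjusted p = 0.018), and the difference between the 7 lines passed for it (adjusted p = 2.2e-05). Z00032758-1 (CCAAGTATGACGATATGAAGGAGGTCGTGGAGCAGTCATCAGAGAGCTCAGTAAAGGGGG) fell by 1.06, from 3.02 ± 0.04 to 1.97 ± 0.50 (SE 0.14, adjusted p = 0.000174). For this probe the adjusted p was 0.0558 in the value table of the authors and 0.0612 with the 4 arrays of the line alone. Z00077019-1 (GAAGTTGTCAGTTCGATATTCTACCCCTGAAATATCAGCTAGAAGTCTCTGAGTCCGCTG) fell by 0.98, from 1.45 ± 0.15 to 0.47 ± 0.02 (SE 0.07, adjusted p = 1.1e-07), while in the Tbx3 line it rose by 0.49 (adjusted p = 0.00077). The 10 largest rises ranged from 0.77 to 1.38 and the 10 largest falls from -0.68 to -1.06, and all 20 passed the test of the difference between lines.

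In the Etv5 line the groups did not overlap for 59.1% of all probes, and separate pairs of arrays gave differences correlated across probes at r = 0.56. Against the mean change of the other 6 lines 983 probes passed, with median centring 281, and without the arrays of the Tbx3 line 3915. Leaving out with Dox replicate 1 or 2 gave 488 and 683, leaving out without Dox replicate 1 or 2 gave 1060 and 547, and leaving out either array of the Tbx3 line without Dox gave 2524. With the Cy3 channel alone 679 were higher and 591 lower, and with the GC trend taken out 873 and 855, so that the balance between rises and falls is not settled.

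For the Tbx3 line, 888 probes rose and 1183 fell in the fit over all its arrays, but without Dox replicate 1 lies on another slide, and within the slide that holds the other 3 arrays 95 rose and 97 fell, of which 165 were among the 2071. Z00026897-1 (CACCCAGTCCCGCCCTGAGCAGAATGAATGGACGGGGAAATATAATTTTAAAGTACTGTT) rose from -0.05 ± 0.04 to 0.74 ± 0.10, a change of 0.79 (SE 0.07, adjusted p = 1.1e-05), and within the slide by 0.87 (SE 0.08, adjusted p = 7.0e-05). Its size is uncertain, since only 1 of its 2 arrays with Dox was well above background, and the change was 1.80 with the processed signals of the scanner software and 2.73 with the Cy3 channel alone, while the Cy5 reference differed by 0.90 (adjusted p = 0.0889). It also rose in the Tcl1, Etv5 and Ctbp2 lines, by 0.61, 0.35 and 0.44. Z00019741-1 (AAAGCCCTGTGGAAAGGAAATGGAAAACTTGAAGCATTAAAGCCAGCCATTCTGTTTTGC) fell by 0.76, from -2.22 ± 0.24 to -2.98 ± 0.09 (SE 0.11, adjusted p = 0.00098), and within the slide fell by 0.82 (SE 0.13, adjusted p = 0.00795). This probe rose in the Etv5 line by 0.52 and in the Ctbp2 line by 0.71 (adjusted p = 0.007 and 0.00026).

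The other 2 probes named for the Tbx3 line did not pass within its slide. Z00060375-1 (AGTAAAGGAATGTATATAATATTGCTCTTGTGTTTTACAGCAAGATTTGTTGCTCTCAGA) had the largest change, 1.11 over all arrays, from -1.03 ± 0.97 to 0.08 ± 0.31 (SE 0.31, adjusted p = 0.038), and 0.90 within the slide (adjusted p = 0.38). Z00021863-1 (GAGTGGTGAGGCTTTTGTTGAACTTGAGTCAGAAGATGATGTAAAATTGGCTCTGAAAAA) differed by -0.85, from 0.74 ± 0.59 to -0.12 ± 0.57 (SE 0.21, adjusted p = 0.0225), and by -0.45 within the slide (adjusted p = 0.435). With with-Dox replicate 2 left out, the values of the pair were 0.43 (adjusted p = 0.345) and -0.44 (adjusted p = 0.182). In the test of the difference between lines their adjusted p was 0.391 and 0.161, and with the Cy3 channel alone 0.208 and 0.263. Under the rule for naming probes, the 10 largest rises of the Tbx3 line ranged from 0.67 to 1.11, and 4 of them passed the test of the difference. The 10 largest falls under that rule ranged from -0.66 to -0.85, and 6 passed it. The largest fall of any probe that passed in the line was -0.97. Of all 2071 probes, 54 changed at least 1.5-fold. Over all probes of the line the groups did not overlap for 30.1%, less than by chance. Differences from separate pairs of arrays correlated across probes at r = 0.07. In the Cy5 channel, which holds the same reference RNA on every array, 1295 probes passed between these cultures, against 23 or fewer in each other line.

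The Tbx3 count moved more than that of any other large response with the arrays and settings used. It was 192 without the array on the other slide, 5488 on leaving out with-Dox replicate 1, 7707 on leaving out without-Dox replicate 2, and 585 with slide as a random block. With median centring 3231 probes were higher and 238 lower, which turns the balance between rises and falls, and the 4 arrays of the line alone gave 0 probes in limma, with 7163 at an unadjusted p under 0.05 in the fit over 28 arrays.

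In the Jarid2 line 2 probes rose and 1 fell among 28882 tested. Z00037504-1 (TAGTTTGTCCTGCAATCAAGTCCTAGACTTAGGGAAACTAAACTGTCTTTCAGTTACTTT) rose from 0.04 ± 0.01 to 0.72 ± 0.03, a change of 0.68 (1.60-fold, SE 0.08, adjusted p = 0.00382), and it fell by 0.50 in the Tcl1 line (adjusted p = 0.00079). Z00024628-1 (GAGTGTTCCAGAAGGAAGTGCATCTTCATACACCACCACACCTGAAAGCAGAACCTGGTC) rose by 0.41, from -2.81 ± 0.01 to -2.40 ± 0.07 (SE 0.05, adjusted p = 0.0059), and fell by 0.29 in the Tcl1 line (adjusted p = 0.0023). Z00035658-1 (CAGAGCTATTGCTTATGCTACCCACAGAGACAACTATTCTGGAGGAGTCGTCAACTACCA) fell by 0.37, from -2.25 ± 0.04 to -2.62 ± 0.06 (SE 0.06, adjusted p = 0.0239). Z00035884-1 was next by p with a change of -0.35 that did not pass (adjusted p = 0.127), while the test of the difference between lines passed for it (adjusted p = 2.7e-06).

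At an unadjusted p under 0.05 there were 1401 probes in the Jarid2 line, and separate pairs of arrays gave differences correlated across probes at r = 0.19. The groups did not overlap for 45.3% of all probes. Against the mean change of the other 6 lines 24 probes passed, while median centring, a replicate block and the 4 arrays of the line alone each gave 0. With the Cy3 channel alone 5 probes were higher and 6 lower, and on leaving out with-Dox replicate 2, 0 were higher and 2 lower. Leaving out without Dox replicate 1 gave 8 probes, and leaving out either Tbx3 array with Dox gave 5. Z00037504-1 had an adjusted p of 0.051 on leaving out with-Dox replicate 2 and of 0.064 on leaving out without-Dox replicate 2. Z00024628-1 had an adjusted p of 0.107, 0.081 and 0.195 on leaving out with-Dox replicate 1, with Dox replicate 2 and without Dox replicate 2. The only fall, Z00035658-1, lost its call on leaving out any of the 4 arrays of the line, with adjusted p from 0.076 to 0.46, and had an adjusted p of 0.058 with the Cy3 channel alone and 0.0502 with no filter.

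The response of the Jmjd2c line was mostly a rise, of 104 probes, with a fall of 16 among 28883 tested. All 11 probes that changed at least 1.5-fold rose, 3 of them at least 2-fold. Z00076654-1 (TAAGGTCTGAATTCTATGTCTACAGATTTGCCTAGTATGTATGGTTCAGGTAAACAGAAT) rose from 1.56 ± 0.03 to 2.94 ± 0.01, a change of 1.38 (2.60-fold, SE 0.11, adjusted p = 5.6e-07). Z00046266-1 (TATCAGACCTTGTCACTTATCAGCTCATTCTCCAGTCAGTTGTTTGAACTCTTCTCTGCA) rose from 0.76 ± 0.03 to 2.01 ± 0.06 (2.38-fold, SE 0.07 log2, adjusted p = 5.4e-09), and its adjusted p was 0.271 with the processed signals of the scanner software, where the log2 change was 1.08. In the Cy5 reference channel Z00076654-1 differed by 0.64 and Z00046266-1 by 1.11, neither past the test (adjusted p = 0.999 for both), against 1.85 and 2.11 with the Cy3 channel alone. The third probe with a change of at least 2-fold, at 1.16, passed in the Cy5 channel with 1.40 (adjusted p = 0.00848), so that the size of these 3 rises is uncertain. Z00065408-1 (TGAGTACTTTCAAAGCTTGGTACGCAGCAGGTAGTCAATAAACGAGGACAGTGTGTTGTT) fell by 0.52, from 0.42 ± 0.02 to -0.10 ± 0.08 (SE 0.09, adjusted p = 0.0079), and fell by 0.61 in the Tcl1 line (adjusted p = 0.00017), while it rose by 0.71 in the Ctbp2 line (adjusted p = 2.6e-05). Z00028557-1 (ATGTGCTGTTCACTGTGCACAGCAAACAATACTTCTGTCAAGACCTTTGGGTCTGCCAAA) fell by 0.44, from -0.55 ± 0.09 to -0.98 ± 0.01 (SE 0.08, adjusted p = 0.0221). The 10 largest rises ranged from 0.61 to 1.38 and the 10 largest falls from -0.33 to -0.52, and 19 of the 20 passed the test of the difference between lines.

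In the Jmjd2c line the groups did not overlap for 43.3% of all probes, and separate pairs of arrays gave differences correlated across probes at r = 0.30. The count was 16 with median centring, 67 with the processed signals of the scanner software, 216 in the value table of the authors, and 444 without the arrays of the Tbx3 line. Leaving out with Dox replicate 1 or 2 gave 29 and 53, leaving out without Dox replicate 1 or 2 gave 43 and 34, and leaving out either Tbx3 array with Dox gave 200. Z00065408-1 had an adjusted p of 0.116, 0.076 and 0.178 on leaving out with-Dox replicate 1, with Dox replicate 2 and without Dox replicate 2, and Z00028557-1 one of 0.064 to 0.372 on leaving out any of the 4 arrays of the line. With the Cy3 channel alone their adjusted p was 0.0791 and 0.0643, and with that channel quantile normalized 0.045 and 0.0713.

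The Ctbp2 line had the largest number of strong changes, and these were mostly rises. Without Dox 971 probes rose and 584 fell among 28884 tested, and of the 150 that changed at least 1.5-fold 136 rose and 14 fell, with 17 changed at least 2-fold. Z00059689-1 (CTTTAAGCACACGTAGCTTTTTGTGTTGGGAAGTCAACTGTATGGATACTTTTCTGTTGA) rose from -0.53 ± 0.01 to 1.37 ± 0.02, a change of 1.89 (3.72-fold, SE 0.10, adjusted p = 5.7e-10). Z00074822-1 (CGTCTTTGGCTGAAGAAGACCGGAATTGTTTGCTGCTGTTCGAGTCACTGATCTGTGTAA) rose by 1.99, from 0.27 ± 1.17 to 2.26 ± 0.05 (SE 0.33, adjusted p = 0.00062). Its replicates with Dox lay apart, at 1.09 and -0.56, so that its rise was 1.16 without the latter and 2.81 without the former. Its adjusted p was 0.130 in the value table of the authors, 0.105 with the 4 arrays of the line alone and 0.0707 in the test of the difference between lines. Z00036170-1 (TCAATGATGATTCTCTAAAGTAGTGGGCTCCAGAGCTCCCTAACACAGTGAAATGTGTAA) fell by 0.89, from 1.47 ± 0.02 to 0.58 ± 0.07 (SE 0.08, adjusted p = 7.8e-07). Z00074836-1 (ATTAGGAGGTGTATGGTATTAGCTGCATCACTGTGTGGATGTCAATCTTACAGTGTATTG) fell by 0.84, from -0.05 ± 0.03 to -0.89 ± 0.00 (SE 0.06, adjusted p = 1.3e-08). The same probe fell by 0.37 in the Tcl1 line (adjusted p = 0.00041) and rose by 0.74 in the Etv5 line (adjusted p = 3.7e-07) and by 0.32 in the Jmjd2c line (adjusted p = 0.0138).

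The 10 largest rises of the Ctbp2 line ranged from 1.21 to 1.99, and 9 of them passed the test of the difference between lines, while the 10 largest falls ranged from -0.65 to -0.89, and 8 passed it. The groups did not overlap for 54.5% of all probes, and separate pairs of arrays gave differences correlated across probes at r = 0.49. With median centring 488 probes passed, and without the arrays of the Tbx3 line 3070. Leaving out with Dox replicate 1 or 2 gave 1029 and 857, and leaving out without Dox replicate 1 or 2 gave 817 and 828.

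In the Mettl5 line 6 probes rose and 1 fell among 28883 tested. Z00037578-1 (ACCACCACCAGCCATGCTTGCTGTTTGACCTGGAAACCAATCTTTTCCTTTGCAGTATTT) rose from -0.42 ± 0.05 to 0.21 ± 0.11, a change of 0.64 (1.56-fold, SE 0.09, adjusted p = 0.0147). The same probe rose in the Tcl1, Etv5, Jmjd2c and Ctbp2 lines, by 0.32, 0.82, 0.46 and 0.77, and fell by 0.39 in the Tbx3 line (adjusted p = 0.013). Z00072898-1 (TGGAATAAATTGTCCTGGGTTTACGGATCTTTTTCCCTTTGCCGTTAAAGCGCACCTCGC) rose at least 1.22-fold to 0.09 ± 0.08 (adjusted p = 0.0274), as it was not well above background on either array with Dox. Z00030644-1 (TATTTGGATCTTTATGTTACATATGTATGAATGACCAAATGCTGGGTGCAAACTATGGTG) fell by 0.41, from 0.69 ± 0.07 to 0.28 ± 0.01 (SE 0.06, adjusted p = 0.0274), and it fell by 0.53 and 0.68 in the Tcl1 and Etv5 lines and rose by 0.64 in the Tbx3 line. Each of the 7 probes also passed in at least 1 other line.

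Against the mean change of the other 6 lines, 0 probes passed in the Mettl5 line in limma. In its own comparison 1465 had an unadjusted p under 0.05, and separate pairs of arrays gave differences correlated across probes at r = 0.31. The groups did not overlap for 46.3% of all probes. The count was 0 with median centring and with the 4 arrays of the line alone, 2 with no filter, 1 with a replicate block, 11 with the GC trend taken out, 80 in the value table of the authors, and 89 without the arrays of the Tbx3 line. It was 3 on leaving out with-Dox replicate 1 and 1 on leaving out with-Dox replicate 2, all of them lower without Dox, and 3 and 2 on leaving out without-Dox replicates 1 and 2. It was 3 without any single array of the Etv5 line, 2 without either Ctbp2 array without Dox, 14 without either Tbx3 array without Dox and 28 without either Tbx3 array with Dox. Z00037578-1 kept its call in 1 of 4 of the fits that leave out an array of the line, with adjusted p from 0.021 to 0.26, and Z00072898-1 and Z00030644-1 in 0 of 4, with adjusted p from 0.088 to 0.39 and from 0.11 to 0.42. Z00030644-1 had an adjusted p of 0.105 with the processed signals of the scanner software and 0.146 with the Cy3 channel alone.

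**Figure D1:**
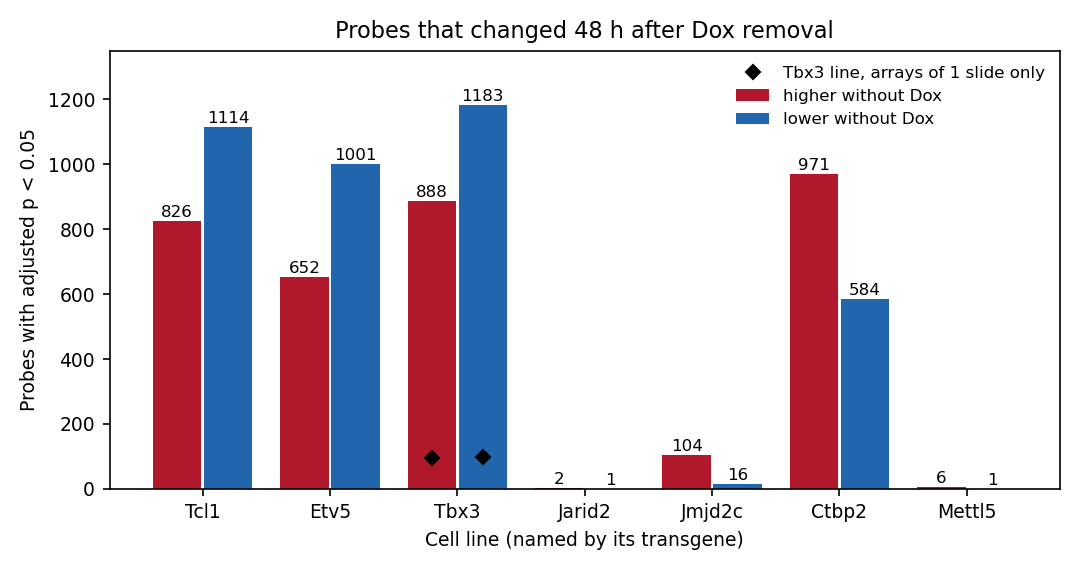
Number of probes with adjusted p under 0.05 in each line, with bars for those higher (red) and lower (blue) without Dox than with Dox, 2 arrays per culture. Diamonds give the Tbx3 line with the arrays of 1 slide only, 95 higher and 97 lower, against 888 and 1183 with all 4 arrays.

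**Figure D2:**
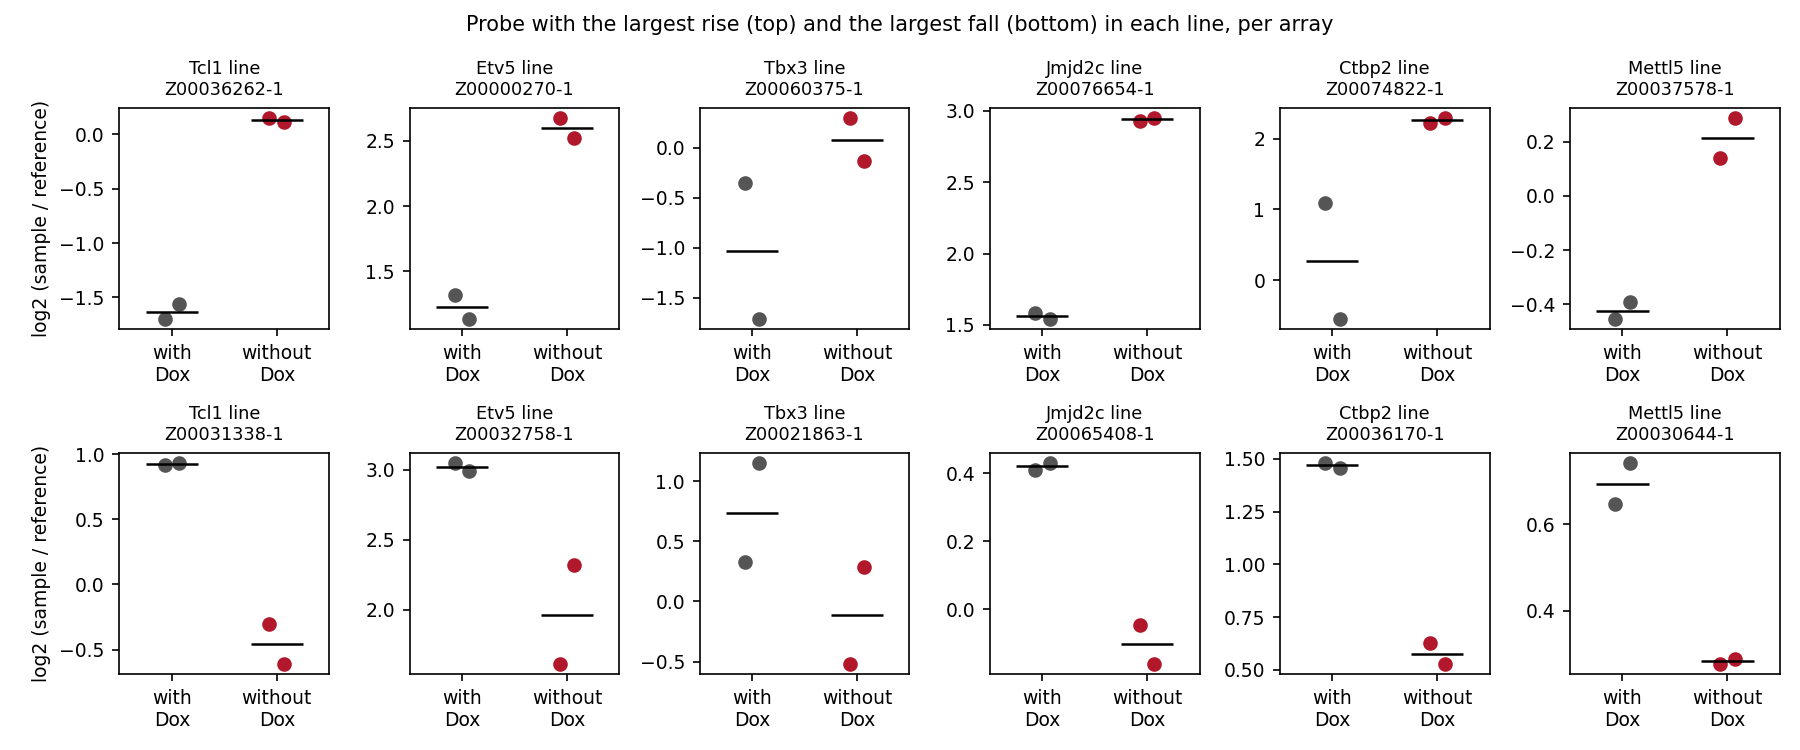
Log2 ratio of sample over reference per array (points, horizontally spread for sight) and group mean (line) for the probe with the largest rise (top) and the largest fall (bottom) of 6 lines, with Dox (grey) and without Dox (red), each panel on its own scale. The with Dox replicates of Z00074822-1 in the Ctbp2 line lie at 1.09 and -0.56, while those of Z00036262-1 in the Tcl1 line differ little, with a mean of -1.63 ± 0.10.

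No probe passed as changed in the 7 lines together in limma with the line as replicate, and 1777 had an unadjusted p under 0.05, where 1444 would by chance. The comparison asks what Dox removal does whatever the transgene. Z00040042-1 (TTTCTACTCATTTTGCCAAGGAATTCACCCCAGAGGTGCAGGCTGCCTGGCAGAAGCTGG) had the lowest adjusted p, 0.321, with higher values without Dox in 7 of 7 lines. It was not well above background on any array with Dox, so that no size is given. The change had the same sign in all 7 lines for 645 probes, 254 higher and 391 lower, or 2.23% of those tested, where chance gives 1.56%. With the wells as replicates, the average of the 7 changes passed for 1021 probes, 531 higher and 490 lower, but 143 of these had the same sign in all lines.

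The lines differed in their response for 3002 probes, 10.4% of those tested, by limma's test of the difference. Their median range over the 7 lines was 0.52 (log2), and for 163 the range was at least 2-fold. Z00036262-1 had the widest range, 2.39 (adjusted p = 3.5e-08), with a rise of 1.76 in the Tcl1 line and a fall of 0.63 in the Tbx3 line. The latter is over all arrays of the Tbx3 line, 1 of them on another slide. In the other 5 lines its changes, between -0.10 and 0.11, did not pass. Z00062714-1 (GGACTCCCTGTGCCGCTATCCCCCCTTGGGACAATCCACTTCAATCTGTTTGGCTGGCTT) rose by 1.79 in the Ctbp2 line, 0.89 in the Etv5 line and 0.48 in the Jmjd2c line and fell by 0.58 in the Tcl1 line and by 0.19 in the Tbx3 line (adjusted p = 7.5e-12 for the difference). Of the 5655 probes that passed in any line, 4350 passed in 1 line, 989 in 2, 251 in 3 and 65 in 4 or more. Among those in several lines, 460 changed in 1 direction and 845 in both. Of the latter 843 passed the test of the difference, which their selection by opposite calls in the same fit made nearly certain. The excess of both directions came from the calls of the Tbx3 line, since among the other 6 lines in the same fit 520 probes changed in 1 direction and 402 in both. With median centring 1008 probes passed that test, and in the value table of the authors 5547. Without the arrays of the Tbx3 line 4957 passed, 5506 on leaving out its with-Dox replicate 1, and 7604 on leaving out its without-Dox replicate 2.

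The lines also differed widely with Dox. There, 22291 probes, or 77.2%, differed between the 7 lines, 1998 with a range of at least 2-fold and 183 of at least 4-fold. Z00070002-1 had a range of 6.03, from -3.71 in the Etv5 line to 2.32 in the Ctbp2 line. On removal of Dox Z00070002-1 fell by 0.38 in the Ctbp2 line (adjusted p = 0.015), and no other change of this probe in a line passed. Each line is a single clone on a slide of its own, so that line, clone and slide cannot be told apart in this comparison.

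The changes of different lines had a median r of 0.08 across probes over the 21 pairs of lines, and no test was made of r. The r between lines is limited by how well the change of each line repeats. Separate pairs of arrays gave r of 0.07 in the Tbx3 line, 0.19 in Jarid2, 0.30 in Jmjd2c, 0.31 in Mettl5, 0.49 in Ctbp2, 0.56 in Etv5 and 0.58 in Tcl1. A low r between lines thus does not show that their responses were unlike. Etv5 and Mettl5 were the most alike, with r = 0.42, followed by Etv5 and Jmjd2c and by Jmjd2c and Mettl5, each at r = 0.25. With the Cy3 channel alone the r of these pairs was 0.17, 0.14 and 0.10, and with the processed signals of the scanner software 0.19, 0.10 and 0.12. Tbx3 ran against Tcl1, Etv5, Jmjd2c and Mettl5, with r from -0.18 to -0.23, but from -0.05 to -0.14 with the Cy3 channel alone and from -0.03 to -0.21 with median centring. For all of these pairs the covariance was larger in size with the Cy3 channel alone, as for Etv5 and Mettl5 (0.0109 against 0.0043) and for Tbx3 and Etv5 (-0.0106 against -0.0041). Within its slide the r of Tbx3 with Etv5 was -0.32, with Mettl5 -0.24, with Jmjd2c -0.17 and with Tcl1 -0.14. In the Etv5 and Ctbp2 lines 159 probes rose in both and 93 fell in both, where independent calls would give 21.9 and 20.2, while 40 rose in Etv5 and fell in Ctbp2 (13.2 for independent calls) and 55 did the reverse (33.7). The Tcl1 and Etv5 lines shared 179 falls and 89 rises, where independent calls would give 38.6 and 18.6, and 75 fell in Tcl1 and rose in Etv5 (25.1) and 38 did the reverse (28.6), at r = 0.10. For Tcl1 and Ctbp2 all 4 counts lay above those of independent calls, with r = -0.02, as 182 fell in Tcl1 and rose in Ctbp2 (37.5), 60 did the reverse (16.7), 65 rose in both (27.8) and 80 fell in both (22.5). Independent calls are a low bar, since the model gives each probe a single residual spread for all lines. Probes with a small spread pass more often in every line and in either direction, so that an excess alone shows no shared response. The median r was 0.03 on leaving out the Tbx3 with-Dox replicate 2, 0.05 on leaving out its without-Dox replicate 2, and 0.02 with median centring.

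**Figure D3:**
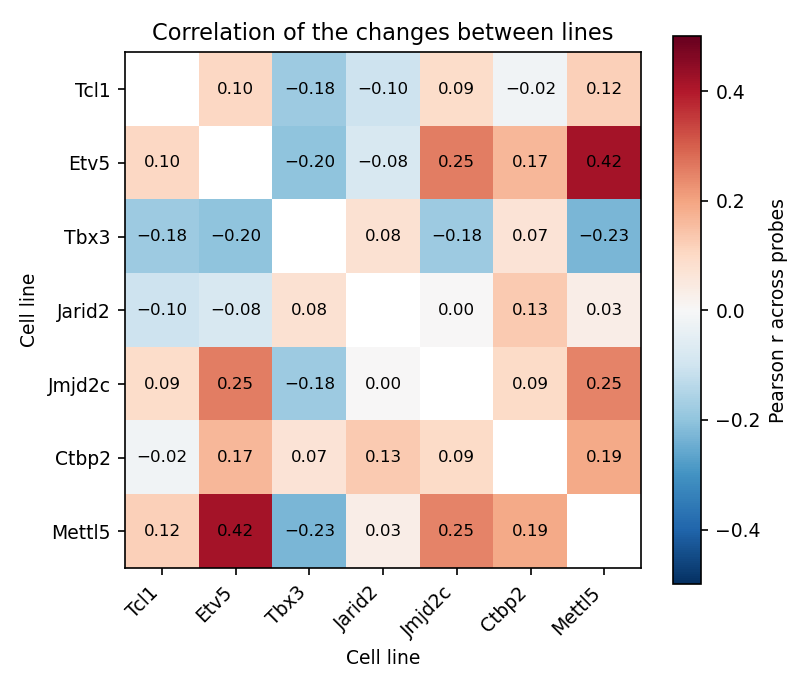
Pearson's r across probes of the log2 changes (without Dox minus with Dox) for each pair of the 7 lines, named by transgene on both axes, with colour from blue (negative) to red (positive). The highest value is 0.42 for Etv5 and Mettl5 and the lowest -0.23 for Tbx3 and Mettl5.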

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

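The tests of the Tbx3 count within its slide and in the reference channel were chosen only after the counts were seen, and the test of the shared response by choices of sign was chosen before. The response to Dox removal differed between the 7 lines for 3002 of the 28884 probes by limma's test of the difference itself, with a range over the lines of at least 2-fold for 163 of them. Z00036262-1 had the widest range, 2.39 on the log2 scale (adjusted p = 3.5e-08), with 2 arrays per culture in each line. It ran from a rise of 1.76 in the Tcl1 line to a fall of 0.63 in the Tbx3 line over all its arrays, 1 of them on another slide. Z00062714-1 had a range of 2.37 (adjusted p = 7.5e-12), from a rise of 1.79 in the Ctbp2 line to the Tcl1 line, where it fell by 0.58. Of 845 probes that passed as higher in a line and as lower in another, 843 also passed the test of the difference, which their selection by opposite calls made nearly certain. Without the calls of the Tbx3 line, 402 probes passed in both directions, fewer than the 520 that changed in 1 direction in several lines. In the Cy5 channel, which carries the same reference RNA on every array, 1295 probes passed between the cultures of the Tbx3 line, against at most 23 in any other line. Groups of 2 arrays are too small for a test of single arrays that stand apart.

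The 2071 probes of the Tbx3 line may in large part reflect the slide of a single array, since without Dox replicate 1 lies on a slide of its own. Without that array 192 probes passed, 165 of them (7.97%) among the 2071, while in the Tcl1, Etv5 and Ctbp2 lines leaving out 1 array kept at least 28.3%. The 1295 probes that passed in the Cy5 channel, which holds no RNA of the samples, are in line with an effect of the slide or the hybridisation. A response to the Tbx3 transgene stays open for the probes that passed within the slide, where position on the slide is confounded with culture. There, 1 array without Dox is assumed to vary like the other groups. The 2 arrays with Dox on that slide differed with an SD of 0.24 (log2), against at most 0.14 between replicates of the other lines. The spread pooled over lines may thus be too small for the Tbx3 line, and too many of its probes may have passed.

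For the shared response, 1777 probes had an unadjusted p under 0.05 in the test over the 7 lines. Among the 64 choices of which lines to turn in sign, 11 gave as many, the real one included, so that chance cannot be excluded. The highest other choice gave 3922, with the Tbx3 and Jarid2 lines turned, which is more than the real count and points to a structure among the lines that this test does not name. Across probes Tbx3 had a negative r with 4 of the other 6 lines, the lowest -0.23, and Jarid2 with 2, Tcl1 at -0.10 and Etv5 at -0.08. At an adjusted p under 0.05 the real count was 0 and the highest other was 1.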

How the results depend on the processing

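Removal of the GC trend and omission of the Tbx3 line's arrays were chosen after the data were seen. No named change reversed its direction, but the balance of higher and lower probes turned in 5 of 7 lines. For left-out arrays of the line the direction was fixed in advance, since the groups of the named probes did not overlap. The estimated change of a probe also stays the same with Aquantile, either filter, the trended and robust eBayes or a line's arrays alone. It stays the same without the Tbx3 arrays and, outside the Tbx3 line, with slide as a random block, and nearly so with a replicate block. In these settings a reversal was not to be expected, so the lack of one counts only for the other settings. The balance turned in Tcl1 on leaving out without Dox replicate 2 (852 higher, 749 lower), in Etv5 with the Cy3 channel alone (679 and 591), with the GC trend taken out (873 and 855) and at 1.5-fold or more (27 and 22), and in Tbx3 with median centring and at 1.5-fold or more (32 and 22). In Jarid2 it turned with the Cy3 channel alone (5 and 6) and without with-Dox replicate 2 (0 and 2), and in Mettl5 without with-Dox replicate 1 (0 and 3) or 2 (0 and 1). Of 159 counts and correlations under alternatives, 110 stayed within 1.5 times the value reported or within their spread, and 49 did not. For named probes, 301 of 352 values under alternatives stayed past or short of the threshold as reported, and 51 lost their call. When an array of the line was left out, 31 of 104 lost it. Aquantile leaves log ratios unchanged and so tests nothing, yet its values are among those counted as unchanged under alternatives. The shared count was 0 with the line as replicate under every alternative and line left out, and 1021 with the average of the line contrasts over wells. Counts between lines with Dox ranged from 14924 with the authors' value table, where 17837 probes were tested, to 23644 with median centring. The r of Etv5 and Mettl5, 0.42, was 0.19 with the processed signals, 0.17 with the Cy3 channel alone and 0.24 with the authors' value table. The mean of the probes of a gene, the induced genes and the gene lists were not run.

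With median centring in place of loess, 505 probes passed in the Tcl1 line, 281 in Etv5, 3469 in Tbx3 (3231 higher and 238 lower), 0 in Jarid2, 16 in Jmjd2c, 488 in Ctbp2, 0 in Mettl5, and 1008 for the difference in response. The median change of all probes moved by under 0.1 with each scaling. With the scanner's processed signals 67 passed in Jmjd2c (50 higher, 17 lower). With the Cy3 channel alone 902 passed in Tbx3 and 11 in Jarid2. The authors' value table gave 4117 in Tbx3, 22 in Jarid2, 216 in Jmjd2c (134 higher, 82 lower), 80 in Mettl5 and 5547 for the difference. No filter gave 1274 in Tbx3, 75 in Jmjd2c and 2 in Mettl5, with more probes tested. Slide as a random block (correlation 0.347) gave 585 in Tbx3. The replicate block gave 3273 in Tbx3, 0 in Jarid2, 75 in Jmjd2c and 1 in Mettl5. The 4 arrays of a line alone, which leave fewer degrees of freedom, gave 196 in Tcl1, 0 in Tbx3, 0 in Jarid2, 29 in Jmjd2c and 0 in Mettl5. A change of at least 1.5-fold, which by construction keeps fewer, left 113, 49, 54, 1, 11, 150 and 1 in Tcl1, Etv5, Tbx3, Jarid2, Jmjd2c, Ctbp2 and Mettl5. Minus the mean of the other 6 lines, 983 passed in Etv5, 3242 in Tbx3, 24 in Jarid2 and 0 in Mettl5. With the GC trend taken out 11 passed in Mettl5. Without the Tbx3 line's arrays, 4275 passed in Tcl1, 3915 in Etv5, 32 in Jarid2, 444 in Jmjd2c, 3070 in Ctbp2, 89 in Mettl5 and 4957 for the difference. Omission of the Tbx3 arrays leaves the estimated changes of the other 6 lines the same in a group-means model. Only the spread pooled over lines and its degrees of freedom can thus have moved their counts. The counts of these lines in the main fit therefore depend on the noise of the Tbx3 arrays, whose replicates lay furthest apart. Except where the construction or the model is named, the cause was not tested.

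Leaving out each of the 28 arrays in turn gave 908 to 2869 in Tcl1, 488 to 2524 in Etv5, 192 to 7707 in Tbx3, 2 to 8 in Jarid2, 29 to 200 in Jmjd2c, 817 to 2081 in Ctbp2, 1 to 28 in Mettl5, and 2255 to 7604 for the difference. For Tbx3, leaving out without Dox replicate 1 gave 192, without Dox replicate 2 gave 7707 and with Dox replicate 1 gave 5488. The difference count reached 7604 and 5506 without the latter 2 arrays. A group left with 1 array is assumed to vary like the others. Median Cy3 signal was 1.77 to 2.80 times the local background, so that changes of probes near background are the least certain.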

Other observations

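The probe groups above and below the reference and their thresholds, the choice of the Etv5 and Mettl5 pair, and the tests of slide position, of likeness in every line and of narrower log ratios were chosen only after the results were seen. Probes were grouped by their level in ES cells against the reference, which is mostly RNA of other cell types. A probe was above the reference if its mean log2 ratio was at least 1 in the cultures with Dox of the other 6 lines, and below it at -1 or less, among probes well above background on all 28 arrays. In the Tcl1 line, 319 of the 1702 probes above the reference fell, 46 rose and 1337 did not pass, with a median change of -0.08 against 0.00 for all probes (log2, n = 2 arrays per culture). Camera gave an adjusted p of 1.1e-10 with the preset correlation, and an adjusted p of 0.152 with an estimated correlation. In the Cy3 channel alone the adjusted p with an estimated correlation was 0.00117. Of the 3586 probes below the reference in that line, 256 rose and 174 fell, with a median of 0.02 and an adjusted p of 0.0971. In the Tbx3 line, 160 of the 1686 probes above the reference rose and 45 fell, with a median of 0.08, an adjusted p of 1.2e-06 with the preset correlation and an adjusted p of 0.272 with an estimated correlation. Relative to all probes the median was 0.0814, and 0.0456 in the Cy3 channel alone (adjusted p = 0.0218 with the preset correlation and 0.167 with an estimated correlation). That value is confounded with the slide of 1 array. In the Jarid2 line the 3584 probes below the reference had a median of 0.03 with an adjusted p of 7.1e-07, and 0.152 as the adjusted p with an estimated correlation. In the Cy3 channel alone these were 0.0218 and 0.314. In that group 1 probe rose and 1 fell. The group above the reference in the Mettl5 line had a median of -0.02, with an adjusted p of 0.0387 and, with an estimated correlation, an adjusted p of 0.691. It did not pass at the preset correlation in the Cy3 channel alone (adjusted p = 0.136) or with the GC trend taken out (0.0738). None of its 1598 probes passed on its own. The other 10 tests of a group in a line did not pass at the preset correlation, though in the Cy3 channel alone the group below the reference in the Etv5 line did, with an adjusted p of 0.0218, and of 0.314 with an estimated correlation.

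The changes of the Etv5 and Tbx3 lines ran against each other across probes. Of the probes that passed in both lines, 162 were higher without Dox in the Etv5 line and lower in the Tbx3 line, and 179 the reverse, where independent calls would give 26.7 and 30.8. In the same direction there were 5 and 5, against 20.0 and 41.0. With the Tbx3 line restricted to the 3 arrays on 1 slide, r was -0.32 and 101 probes were opposite, against 5.48 for independent calls, and 2 had the same direction. The 2 lines share no arrays. Independent calls are a low bar, as each probe has a single residual spread for all lines, but this would raise the counts in either direction. The spread pooled over lines may be too small for the Tbx3 line, so that too many of its probes may have passed. Single probes were mixed in the Tbx3 fit inside its slide, with 2 arrays with Dox and 1 without. Among probes that passed there and over all arrays, Z00026897-1 had the largest rise, 0.87. It also rose in the Etv5 line, by 0.35 (adjusted p = 0.0038). Z00058717-1 had the largest fall, -0.85, and its change of 0.11 in the Etv5 line did not pass (adjusted p = 0.698). The second of each kind ran against the Etv5 line. Z00063157-1 rose in the Tbx3 line by 0.70 (SE 0.12) and fell by 0.52 in the Etv5 line (adjusted p = 0.0092). Z00021597-1 fell by 0.82 in the Tbx3 line (SE 0.11) and rose by 0.35 in the Etv5 line (adjusted p = 0.0461). These probes were chosen after their values were seen.

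A candidate explanation for the fall of probes above the reference in the Tcl1 line is narrower log ratios on the arrays without Dox, under which probes below the reference would rise by a like amount. Their median rise relative to all probes was 0.0194, against -0.08 for the probes above it, or 0.245 times that fall. The quartiles give the spread over probes and not the error of the median, so they cannot decide this. The SD of the log ratios over tested probes was 0.988 and 0.981 on the arrays with Dox and 0.979 and 0.972 on those without. These values argue against narrower ratios as the whole of the fall, while a part of it stays open. A trend with GC content is argued against by the median of -0.0837 relative to all probes after that trend was taken out (adjusted p = 2.2e-11 with the preset correlation, and an adjusted p of 0.0555 with an estimated correlation). A difference in the reference channel is argued against by the median of -0.0888 relative to all probes in the Cy3 channel alone. The transgene itself and slide position acting on Cy3 stay open, untested.

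The Etv5 and Mettl5 changes, with r of 0.42 the highest of the 21 pairs, may share a technical source, although the lines lie on different slides. Slide position acting on both channels is argued against by r of -0.0012 in the Cy5 reference channel, GC content by r of 0.410 after its trend was taken out, and loess by r of 0.367 with median centring. The r fell to 0.173 in the Cy3 channel alone and to 0.188 with the processed signals of the scanner software, while the covariance was 0.0109 and 0.0108 there, against 0.00432. An effect of how the signals were processed is thus not excluded. A response to Dox removal alike in every line was tested by the lowest r between lines, -0.228 for Tbx3 and Mettl5. This cannot decide, since differences from separate pairs of Tbx3 arrays had r of only 0.07. A common part can also lie under changes of each line's own. Slide position acting on the Cy3 channel alone, the processing of the signals, a part common to all lines, and a response that these 2 lines share, stay open.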
